A study of Homo sapiens with 6 samples.

How the data were processed

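Poly-A RNA was sequenced from BJ cells, an established line of human foreskin fibroblasts, on day 8 after infection with lentivirus carrying 2 polycistronic constructs, OCT4 with SOX2 and KLF4 with MYC. The cells had been sorted by their surface CD13 (gene ANPEP) and CD201 (gene PROCR) into 3 groups: negative for both proteins (double-negative), negative for CD13 and positive for CD201 (CD201-only), and positive for both (double-positive). Each group has 2 libraries, 6 in all, and every library was placed in its group from the labels. Libraries were stranded, and cells grew first in serum and then in medium for human embryonic stem cells, per the labels' protocols.

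The authors deposited 1 table of FPKM values, with 27788 gene symbols and 6 library columns, and 0 columns were left unassigned. The deposited FPKM values came from STAR alignments and Cuffnorm on the human builds hg19 and GRCh37, per the submitters' processing notes. The aligner options, the annotation, the tool versions and Cuffnorm's scaling option are not given in the sources used here. Cuffnorm can rescale libraries, and the values were used as deposited in the main analysis.

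Each value was taken as log2 of FPKM plus a pseudocount of 1. Genes with a mean of at least 1 FPKM over the 6 libraries were tested, 12210 genes in all. One model per gene with a coefficient per group was fitted in limma 3.58.1 under R 4.3.3, with a variance trend over expression level. Each of the 3 pairwise comparisons was adjusted by Benjamini-Hochberg over its genes, and a gene was called at an adjusted p under 0.05. The fit has 3 residual degrees of freedom and a prior worth 3.95. A moderated F test asked whether a gene differed among the 3 groups. Log2 changes are the first group minus the second on this scale. It understates fold changes, most for genes near or under 1 FPKM but also at several FPKM. CDKN2B, at 7.096 FPKM in double-positive and 3.067 in double-negative cells, has a ratio of 2.31 but a log2 change of -0.9945. Thresholds of 2-fold and 4-fold are applied on this scale. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 read the table and drew the plots.

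Gene sets were 28 lists of marker and pathway genes, and 25 of them had at least 5 tested genes. Those were compared with all other genes by limma's camera at a preset correlation of 0.01, adjusted over the lists, and again with a correlation estimated from the data. With an estimated correlation camera tests on the 3 residual degrees of freedom, and with a preset one on about the number of genes. Calls lost with an estimated correlation therefore need not be due to correlation between genes. limma's fry was also run, which tests only whether the genes of a list move one way. Of the listed genes, 2 were not found in the table. Some lists share genes: of 31 genes in the list of stress from cell handling, 6 are in another list, of 15 AP-1 genes 5, of 25 YAP and TEAD targets 5, of 24 trophoblast and amnion genes 7, and of 21 mesoderm and endoderm genes 4. The p53 list shares 3 genes, and the endothelial, epithelial, fibroblast, keratinocyte, mesenchymal, pluripotency, TGF-beta and unfolded protein lists share 1 each. The remaining lists share 0.

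Named genes follow a rule. In each comparison they are ANPEP, PROCR, POU5F1, SOX2, KLF4 and MYC, the 6 largest rises and the 6 largest falls, and the members with the largest change from each list with at least 3 called members. A gene among the largest changes had to be called, to have groups that did not overlap, and to reach a mean of at least 5 FPKM in the higher group. From each list up to 2 members were taken, or up to 4 from the fibroblast, mesenchymal, epithelial, pluripotency, AP-1 and YAP lists. Genes on the Y chromosome and XIST were left out, and some genes that the rule names are not reported here. The groups, the tests, the lists, this rule and most alternatives were set before the data were examined. A correction for GC content, an average of the double-negative libraries and the removal of small RNA genes were chosen after seeing the data.

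Counts were not used here, so depth was approximated. Steps between the lowest FPKM values of a gene correspond to single fragments. On that basis the relative depth ran from 0.730 to 1.0, which corresponds to about 12.1 to 16.6 M fragments (M, mega). The scale rests on 34 genes with transcripts of at least 3000 nt and an assumed fragment of 200 nt, and its interquartile range for the first double-negative library is 9.66 to 16.6 M. At the median gene, replicates of one group differed by little more than counting. The median coefficient of variation was 0.967% to 1.97% for genes over 100 FPKM and 5.32% to 6.38% for genes from 1 to 10 FPKM. For genes with 300 to 3000 estimated fragments, a median-based squared difference between replicates was 0.981 to 1.51 times its counting variance. Between the replicate 1 libraries of different groups it was 10.3 to 30.3 times. For genes with 30 to 300 fragments it was 0.961 to 1.25 between replicates. Double-positive replicates also differed along transcript GC content (Spearman correlation across genes 0.291), which these medians do not show. Nor do they show a difference shared by the replicates of CD201-only and double-positive cells. Over 4691 well expressed genes, replicate differences of these 2 groups correlated at 0.399, against -0.0412 and -0.0433 for the other pairs of groups. The replicates may still be technical, and the labels do not say which. If so, the adjusted p values describe the sorted samples rather than repeated reprogramming experiments.

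In simulated data of 12210 genes, 335, 335 and 330 genes were changed 1.2-, 1.5- and 2-fold over 5 runs, far fewer than were called in the data. Fewer true changes make the Benjamini-Hochberg threshold stricter, so recovery in the data may differ. The fit was tested on these simulated data. For the double-negative against the double-positive group it recovered 29.6% of genes changed 1.2-fold, 76.4% of those changed 1.5-fold and 90.9% of those changed 2-fold, with at most 6 false calls in each of 5 runs. For the double-negative against the CD201-only group recovery was 30.5%, 77.9% and 91.5%, with at most 11 false calls. The fibroblast list, lowered by 0.5, was called by camera in 10 of 10 runs. Of the other lists 0 were called, in a count that left out the TGF-beta and YAP lists. Simulated genes varied independently, so these runs do not test how correlation between genes affects camera. The overlap of calls between comparisons that share the double-positive libraries was set against 20 simulated runs.

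The alternatives were pseudocounts of 0.1 and 0.5, no filter, a filter at 5 FPKM, quantile normalization, median-ratio rescaling, limma without the trend and with a robust trend, the replicate number as a block, each library left out, only the libraries compared, a minimum change of 2-fold, and the alternatives named above. For the GC correction, transcript GC content and length were taken by symbol from GENCODE 29, matched for 97.9% of the tested genes, and used without coordinates. Reads from the lentiviral constructs cannot be separated from those of the endogenous genes in FPKM per gene.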

Results

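Gene expression was measured in BJ fibroblasts on day 8 of reprogramming towards pluripotency, sorted into double-negative, CD201-only and double-positive cells, with 2 libraries per group. Reprogramming converts fibroblasts, through loss of their identity, into cells like embryonic stem cells, and the series title concerns how accessible chromatin changes on that path. The FPKM values of each library summed to 513206 and 511947 in the double-negative group, 521352 and 520703 in the CD201-only group, and 489358 and 489152 in the double-positive group. Between 11983 and 12168 genes reached 1 FPKM per library, and the 10 highest genes took 8.42% to 9.17% of the sum. Approximate depths were 13.0 and 15.2 M fragments, 13.6 and 16.6 M, and 12.1 and 13.7 M in the same order. Values are mean FPKM ± SD with n = 2, and log2 changes are limma estimates with their standard error (SE) and adjusted p.

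The transcripts of the sorted proteins followed the sort. ANPEP, which encodes the aminopeptidase CD13, was at 35.96 ± 0.347 FPKM in double-negative, 28.89 ± 0.216 in CD201-only and 155.3 ± 3.65 in double-positive cells. PROCR, which encodes the protein C receptor CD201, was at 17.31 ± 0.948, 47.45 ± 2.34 and 51.93 ± 0.842. ANPEP fell by 2.08 (SE 0.0303, adjusted p = 3.01e-08) in double-negative and by 2.39 (adjusted p = 1.6e-08) in CD201-only against double-positive cells. PROCR fell by 1.53 (SE 0.0498, adjusted p = 6.32e-07) in double-negative against double-positive cells. The change of PROCR in CD201-only cells was -0.13 (adjusted p = 0.0606). It passed the threshold under median-ratio rescaling (-0.21, adjusted p = 0.00936) and quantile normalization (-0.18, adjusted p = 0.0178). After the GC correction (-0.21, adjusted p = 0.0103) and with the replicate number as a block (-0.13, adjusted p = 0.0222) it passed too. Without CD201-only replicate 2 the change was -0.18.

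**Figure D1:**
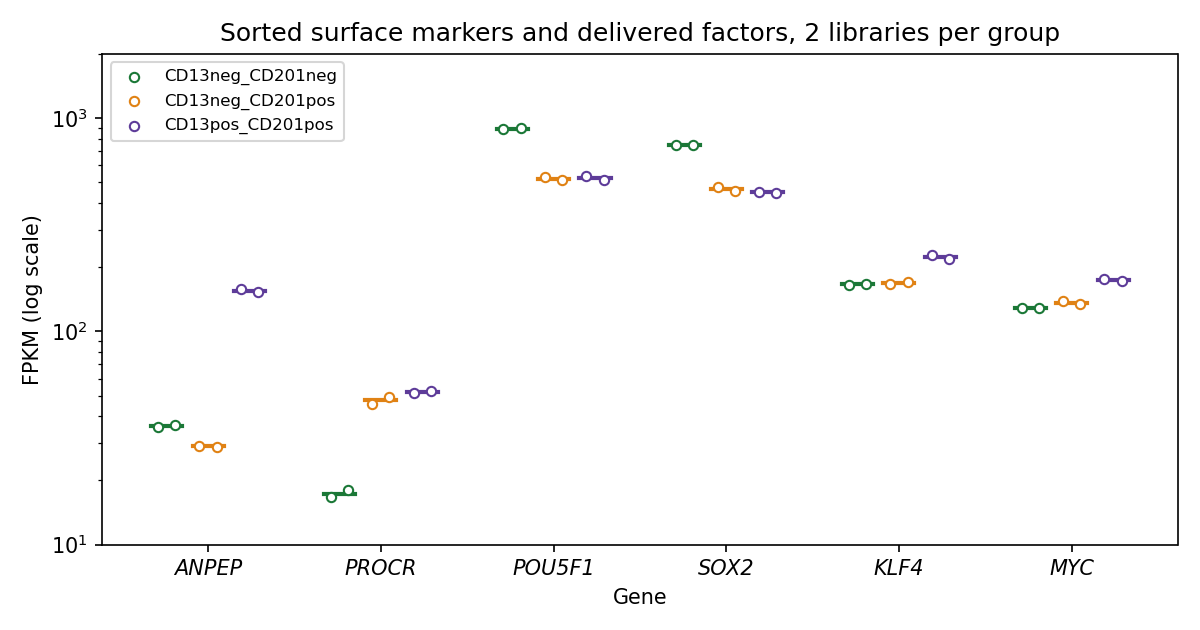
FPKM of the sorted genes ANPEP and PROCR and of the delivered factors in each library (points) with group means (bars), on a log axis. POU5F1 and SOX2 are highest in double-negative cells and KLF4 and MYC are highest in double-positive cells.

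The groups were separated well beyond their replicates. The lowest correlation within a group was 0.9919 and the highest between groups 0.9807. The first principal component held 64.2% of the variance and parted double-positive from the other cells, and the next held 22.7% and parted double-negative from CD201-only cells. Of 12210 genes, 8912 differed among the groups by limma's F test.

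Double-negative cells were compared with double-positive cells to ask what distinguishes cells sorted as negative for both surface proteins from those positive for both. Of 37 fibroblast and matrix genes 32 were lower, and of 22 genes of pluripotent cells 20 were higher, and camera called both lists, with adjusted p = 0.053 each with an estimated correlation. The tissue inhibitor of metalloproteinases TIMP3 fell from 318.3 ± 5.21 to 37.17 ± 0.404 FPKM (log2 change -3.07, SE 0.0369, adjusted p = 1.9e-08). COL1A1, the main chain of type I collagen, fell from 1691 ± 42.3 to 305.3 ± 2.98 FPKM (-2.47). LIN28A, an RNA-binding protein of pluripotent cells, rose from 1.672 ± 0.353 to 11.52 ± 0.8 FPKM (2.23, adjusted p = 2.48e-06), and GDF3, a signalling ligand of pluripotent cells, rose from 16.39 ± 1.06 to 60.78 ± 1.2 FPKM (1.83).

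The delivered factors moved in opposite directions. POU5F1, which encodes OCT4, rose from 524.1 ± 16.2 to 893.4 ± 3.13 FPKM (0.77, SE 0.0291, adjusted p = 1.15e-06) and SOX2 from 450.1 ± 2.77 to 746.7 ± 0.351 FPKM (0.73). KLF4 fell from 223.3 ± 6.0 to 166.1 ± 1.81 FPKM (log2 change -0.43, adjusted p = 1.22e-05) and MYC from 174.6 ± 2.47 to 128.3 ± 0.0919 FPKM (-0.44). These values may include reads from the vectors, and POU5F1 also has expressed pseudogenes. The largest falls were in KRT14, a keratin of basal epidermis, from 29.73 ± 0.861 to 1.819 ± 0.172 FPKM (-3.45), MAL, a membrane raft protein (-3.36), ALDH3A1, an aldehyde dehydrogenase, from 130.5 ± 0.85 to 12.48 ± 0.583 FPKM (-3.29), PRELP, a matrix proteoglycan (-3.25), KLK14, a secreted protease (-3.22), and C6orf15, a matrix-binding protein (-3.19). Reads of keratins can be shared between paralogs.

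The largest rises included 3 small nucleolar or Cajal body RNAs, which lack poly-A tails and are measured poorly in poly-A libraries. SCARNA20 was at 33.37 ± 20.0 FPKM and SNORA3B at 31.83 ± 26.1 FPKM in double-negative cells, and both were listed at 0 in the other groups. SNORA57 rose by 2.77 (adjusted p = 0.0287), and the call was lost without double-negative replicate 1 (adjusted p = 0.117) or replicate 2 (adjusted p = 0.0883). It was also lost with a pseudocount of 0.1 (log2 change 4.44, adjusted p = 0.0531), without the filter (adjusted p = 0.0949), in limma without the trend (adjusted p = 0.0595) or with the robust trend (adjusted p = 0.163), and with the double-negative libraries averaged (adjusted p = 0.106). The others were GPC4, a surface proteoglycan, from 2.22 ± 0.0414 to 17.31 ± 1.78 FPKM (2.50), the metallothionein MT1G from 59.93 ± 1.77 to 303.3 ± 14.9 FPKM (2.32), a family whose members share reads, and LIN28A.

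Of 37 tested genes of fibroblast identity and matrix, 5 rose, 32 fell and 0 were not called, with a median of -1.48, and PDGFRB, a growth factor receptor (-2.55), and BGN, a matrix proteoglycan (-2.48), were among the largest falls. camera gave this list an adjusted p = 9.79e-17, and adjusted p = 0.053 with an estimated correlation. Of 22 mesenchymal transcription factor and adhesion genes, 3 rose and 17 fell (median -0.67), among them FOXF1 (-2.08), HIC1 (-2.07), SNAI2 (-1.89) and PRRX1 (-1.87). camera gave an adjusted p = 7.91e-06, and adjusted p = 0.0626 with an estimated correlation. Of 13 contractile genes, 2 rose and 10 fell (median -0.67), with the myosin kinase MYLK at -1.68 and the calponin CNN1 at -1.25 (camera adjusted p = 0.000126, and adjusted p = 0.0626 with an estimated correlation). Of 22 TGF-beta response genes, 1 rose and 18 fell (median -0.84), including LTBP2, a latent TGF-beta binding protein (-2.32), with camera adjusted p = 1.78e-09 and adjusted p = 0.053 with an estimated correlation.

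Genes of inflammation and immediate response were also lower. Of 21 secreted inflammatory genes of senescent fibroblasts, 2 rose and 17 fell (median -1.19), including the collagenase MMP1 (-2.30) and the chemokine CXCL1, from 159.5 ± 3.34 to 35.31 ± 0.623 FPKM (-2.14). camera gave an adjusted p = 1.2e-07, and adjusted p = 0.0626 with an estimated correlation. Of 13 AP-1 genes, 0 rose and 9 fell (median -0.54), with JUNB at -2.03, FOSB at -1.92, FOSL2 at -1.18 and FOSL1 at -1.15 (camera adjusted p = 6.52e-05, and adjusted p = 0.0626 with an estimated correlation). Of 27 genes that respond to cell handling, 5 rose and 16 fell (median -0.28, camera adjusted p = 0.000207, and adjusted p = 0.0626 with an estimated correlation). Of 25 YAP and TEAD targets, 5 rose and 16 fell, or 6 and 17 adjusted over the list alone (median -0.35), with TGFB2 at -1.81, FOXF2 at -1.58, AXL at -1.54 and ARHGEF17 at -1.04. Their camera adjusted p was 0.000207, and adjusted p = 0.0626 with an estimated correlation. Of 24 interferon response genes, 5 rose and 17 fell, or 5 and 18 adjusted over the list alone (median -0.45), with the proteasome subunit PSMB9 at -1.87 and XAF1 at -1.61 (camera adjusted p = 0.000247, and adjusted p = 0.136 with an estimated correlation).

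Proliferation and growth genes were higher. All 31 tested G2 and M-phase genes and all 29 S-phase genes rose, with medians of 0.59 and 0.61. DLGAP5, a spindle protein, rose by 1.12, the kinetochore gene NDC80 by 0.93 and the helicase subunit MCM6 by 1.04. camera gave both lists an adjusted p = 7.7e-08. These became adjusted p = 0.123 for the G2 and M-phase list and adjusted p = 0.053 with an estimated correlation for the S-phase list. Of 40 ribosomal protein genes, 38 rose and 0 fell, or 40 and 0 adjusted over the list alone (median 0.30), among them RPL7 at 0.52 and RPL22 at 0.53, with camera adjusted p = 1.6e-08 and adjusted p = 0.053 with an estimated correlation. Of 39 respiratory chain genes, 29 rose and 0 fell (median 0.23), including CYCS at 0.66 and ATP5F1A at 0.65 (camera adjusted p = 0.00044, and adjusted p = 0.0954 with an estimated correlation). Of 25 p53 targets and CDK inhibitors, 4 rose and 13 fell (median -0.19). CDKN1A, which encodes p21, fell from 677.1 ± 3.27 to 316.6 ± 1.79 FPKM (-1.09) and CDKN2B by 0.99. Their camera adjusted p was 0.00126, and adjusted p = 0.0984 with an estimated correlation.

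Of 22 tested genes of pluripotent cells, 20 rose and 1 fell (median 1.01), including TDGF1, a co-receptor (1.66), and DNMT3B, a DNA methyltransferase (1.51). camera gave an adjusted p = 7.24e-07, and adjusted p = 0.053 with an estimated correlation. NANOG, a core pluripotency factor chosen after its values were seen, was at 3.93 FPKM in double-negative, 4.17 in CD201-only and 1.64 in double-positive cells. Of 43 chromatin regulators, 36 rose and 1 fell (median 0.43), with TET1 at 0.90 and DNMT3L at 0.84 (camera adjusted p = 1.8e-05, and adjusted p = 0.136 with an estimated correlation). Of 25 unfolded protein and amino acid stress genes, 16 rose and 2 fell (median 0.32), with PHGDH at 0.83 and HSP90B1 at 0.68 (camera adjusted p = 0.0119, and adjusted p = 0.0984 with an estimated correlation).

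Markers of other cell types went both ways. Of 20 epithelial genes, 12 rose and 6 fell (median 0.46, camera adjusted p = 0.385). The protease inhibitor SPINT1 (1.36) and the junction genes CLDN6 (1.33) and LSR (1.22) rose, and CLDN4 fell from 28.52 ± 0.514 to 8.666 ± 0.628 FPKM (-1.61). Of 13 keratinocyte markers, 2 rose and 9 fell (median -0.77), with KRT16 at -2.80, and camera adjusted p = 0.000391, and adjusted p = 0.0626 with an estimated correlation. Of 11 endothelial markers, 2 rose and 8 fell (median -0.65), with ROBO4 at -2.21 and KDR at 1.35 (camera adjusted p = 0.00452, and adjusted p = 0.0961 with an estimated correlation). Of 8 blood markers, 2 rose and 4 fell (median -0.43), with CD68 at -2.17 and RUNX3 at -1.55. The camera call of the blood list (adjusted p = 0.0362, and adjusted p = 0.136 with an estimated correlation) was lost under median-ratio rescaling (adjusted p = 0.0993), quantile normalization (adjusted p = 0.0575), the GC correction (adjusted p = 0.162) and without the filter (adjusted p = 0.17).

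camera did not call the other tested lists. Of 24 cholesterol genes, 11 rose and 5 fell (median 0.14, adjusted p = 0.385). Of 24 glycolysis genes, 14 rose and 6 fell (median 0.17, adjusted p = 0.249), with the transporters SLC2A3 at 1.08 and SLC16A3 at -1.16. Of 7 neural genes, 3 rose and 3 fell, with DLL3 at 1.42 and MAP2 at 1.14. The neural median was -0.08 and its mean 0.19, and camera gave the lower direction (adjusted p = 0.817). Of 9 trophoblast and amnion genes, 4 rose and 3 fell, including HAND1 at -1.02 and KRT7 at -0.93. The trophoblast median of 0.02 changed sign under rescaling, and camera gave the lower direction (adjusted p = 0.799). Of 3 mesoderm and endoderm genes, too few to test, FOXA1 rose (1.33) and HAND1 fell.

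limma called 8130 genes between double-negative and double-positive cells, 5136 higher and 2994 lower, a share of 63.2% higher. The median change of all genes was 0.109, and median-ratio rescaling moved it to 0.00294 and the share of higher calls to 48.3%, so small rises are relative to this shift. Of genes called with at least a 2-fold change, 246 rose and 570 fell, and at least 4-fold 8 rose and 93 fell. camera called 20 lists at the preset correlation and 0 with an estimated one, which also uses only 3 residual degrees of freedom, and fry called 24. Of all genes, 8496 had an unadjusted p under 0.05.

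**Figure D2:**
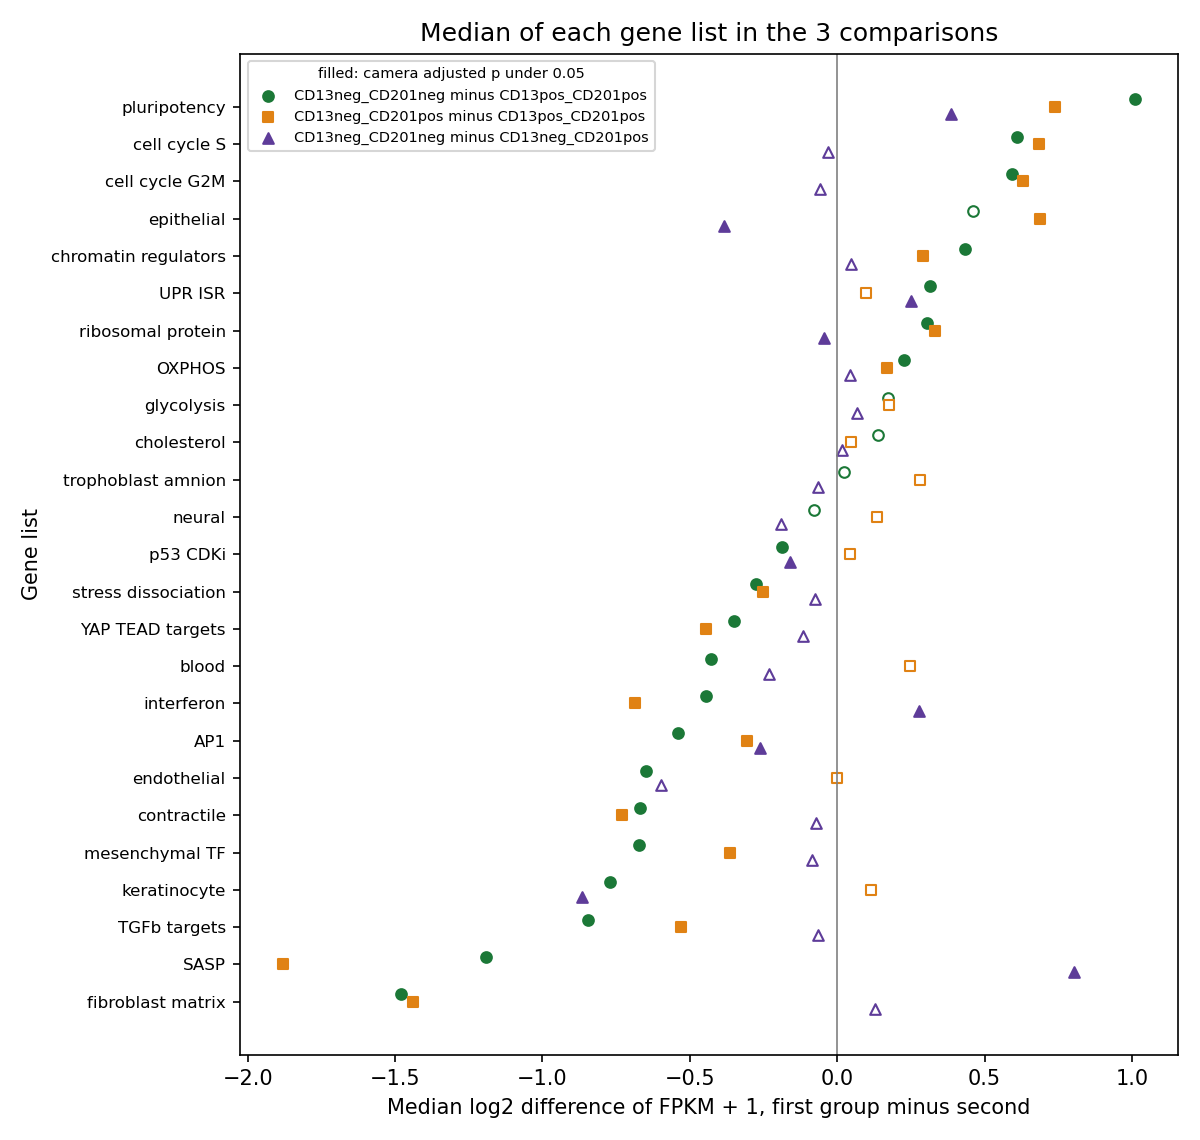
Median log2 difference of the genes of each tested list (points) in the 3 comparisons, with filled points for camera calls. Fibroblast matrix medians are -1.48 and -1.44 against double-positive cells, and pluripotency medians are above 0 in each comparison. Medians of the trophoblast, cholesterol, endothelial, p53, unfolded protein, ribosomal and TGF-beta lists near 0 change sign under at least 1 scaling.

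CD201-only cells were compared with double-positive cells to ask what differs with the absence of CD13 among cells positive for CD201. Of 37 matrix genes 33 and of 21 inflammatory genes 20 were lower. Of 20 epithelial genes 16 and of 22 genes of pluripotent cells 21 were higher, lists that camera called, with adjusted p = 0.0627 and adjusted p = 0.0544 with an estimated correlation. COL5A3, a chain of type V collagen, fell from 50.53 ± 2.51 to 1.92 ± 0.0679 FPKM (log2 change -4.14, SE 0.0557, adjusted p = 1.63e-08). IL1B, an inflammatory cytokine, fell from 186.1 ± 13.1 to 12.15 ± 0.0806 FPKM (-3.83). KRT8, a keratin of simple epithelia, rose from 799.3 ± 24.6 to 1851 ± 24.7 FPKM (1.21, SE 0.0254, adjusted p = 1.41e-07).

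POU5F1 (520.9 ± 14.3 FPKM in CD201-only cells, log2 change -0.01, adjusted p = 0.816) and SOX2 (463.9 ± 14.1 FPKM, 0.04, adjusted p = 0.179) were not called, and POU5F1 was called lower under median-ratio rescaling (-0.09, adjusted p = 0.04) and the GC correction (-0.10, adjusted p = 0.0429). KLF4 fell to 169.1 ± 1.93 FPKM (log2 change -0.40) and MYC to 136.6 ± 2.44 FPKM (-0.35). The other largest falls were in OLFM2, a secreted protein (-3.68), CYP26B1, which degrades retinoic acid (-3.44), KISS1, a secreted peptide (-3.40), and MMP1 (-3.34). The largest rises included SNORA57 (3.37, adjusted p = 0.0152, lost without CD201-only replicate 1, adjusted p = 0.0804) and SNORD22 (1.52, adjusted p = 0.012, lost without CD201-only replicate 2, adjusted p = 0.0661). Both calls were also lost without the filter (adjusted p = 0.0631 and 0.0537) and with limma's robust trend (adjusted p = 0.12 and 0.106). TMEM256-PLSCR3, a read-through transcript that shares exons with its parents, rose by 3.0 (adjusted p = 0.0331), with 5.167 ± 7.31 FPKM in double-positive cells. That call was lost when any double-negative or CD201-only library was left out, with adjusted p from 0.0532 to 0.103. It was also lost with a pseudocount of 0.1 (log2 change 4.67, adjusted p = 0.0592), without the filter (adjusted p = 0.107), in limma without the trend (adjusted p = 0.0671) or with the robust trend (adjusted p = 0.175), with only the libraries compared (adjusted p = 0.0583), and with the double-negative libraries averaged (adjusted p = 0.0573). The tetraspanin TSPAN18, from 18.45 ± 0.163 to 51.22 ± 0.0327 FPKM (1.43), the cadherin CDHR1 (1.41) and ESRG, a long noncoding RNA of pluripotent cells, from 26.27 ± 0.898 to 71.05 ± 0.32 FPKM (1.40), also rose.

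Of 37 fibroblast and matrix genes, 2 rose and 33 fell (median -1.44), including LOXL2, a collagen cross-linker (-3.14), FN1, fibronectin, from 584.9 ± 14.6 to 67.2 ± 2.87 FPKM (-3.10), THBS1, a matrix glycoprotein (-3.10), and COL1A1 (-2.79). camera gave this list an adjusted p = 2.07e-22. Of 21 secreted inflammatory genes, 0 rose and 20 fell (median -1.88, camera adjusted p = 3.57e-12). Of 29 S-phase genes all rose (median 0.69, camera adjusted p = 1.01e-09), with CDCA7 at 0.98. Of 40 ribosomal protein genes, 38 rose and 0 fell (median 0.33, camera adjusted p = 7.67e-11), with RPL7 at 0.49 and RPL8 at 0.46, though RPL8 was at -0.05 under quantile normalization (adjusted p = 0.202). These 4 lists kept their calls with an estimated correlation, each at an adjusted p = 0.0451, and no other list of any comparison did.

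Of 22 mesenchymal genes, 5 rose and 14 fell (median -0.36), including PRRX1 (-2.48), SNAI2 (-1.90), ZEB2 (-1.69) and FOXF1 (-1.50), with camera adjusted p = 0.000738, and adjusted p = 0.0941 with an estimated correlation. Of 13 contractile genes, 2 rose and 10 fell (median -0.73), with CNN1 at -1.52 and LMOD1 at -1.31 (camera adjusted p = 5.81e-05, and adjusted p = 0.0627 with an estimated correlation). Of 22 TGF-beta response genes, 2 rose and 15 fell, or 2 and 16 adjusted over the list alone (median -0.53), with LTBP2 from 43.35 ± 0.331 to 6.356 ± 0.103 FPKM (-2.59). camera gave an adjusted p = 2.52e-07, and adjusted p = 0.0544 with an estimated correlation. Of 25 YAP and TEAD targets, 4 rose and 16 fell (median -0.44), with ANKRD1 (1.22) and TEAD4 (0.90) higher and TGFB2 (-1.45) and FOXF2 (-0.84) lower (camera adjusted p = 0.000142, and adjusted p = 0.0627 with an estimated correlation). Of 13 AP-1 genes, 1 rose and 10 fell (median -0.30), with JUNB at -1.39, FOSB at -1.38, FOSL1 at -0.89 and MAFF at -0.89 (camera adjusted p = 0.000157, and adjusted p = 0.0627 with an estimated correlation). Of 27 genes that respond to cell handling, 7 rose and 16 fell (median -0.25), with EGR1 and EGR2 both at -1.40 (camera adjusted p = 0.00205, and adjusted p = 0.0909 with an estimated correlation). Of 24 interferon response genes, 2 rose and 20 fell (median -0.69), with PSMB9 at -2.48 and XAF1 at -1.68 (camera adjusted p = 5.93e-08, and adjusted p = 0.0866 with an estimated correlation).

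Of 20 epithelial genes, 16 rose and 1 fell (median 0.69), with CLDN6 at 1.26, the protease inhibitor SPINT2 at 1.01 and KRT19, from 34.55 ± 1.83 to 67.14 ± 0.371 FPKM, at 0.94. camera gave an adjusted p = 2.15e-05, and adjusted p = 0.0627 with an estimated correlation. Of 22 genes of pluripotent cells, 21 rose and 1 fell (median 0.74), with TDGF1 at 1.11, LEFTY2 at 1.04, GDF3 at 1.00 and UTF1 at 1.00 (camera adjusted p = 8.72e-07, and adjusted p = 0.0544 with an estimated correlation). All 31 G2 and M-phase genes rose (median 0.63), with CCNB2 at 0.87 and CDC20 at 0.85 (camera adjusted p = 1.28e-09, and adjusted p = 0.108 with an estimated correlation). Of 43 chromatin regulators, 34 rose and 1 fell (median 0.29), with TET1 at 0.87 and KDM1A at 0.78 (camera adjusted p = 2.15e-05, and adjusted p = 0.172 with an estimated correlation). Of 39 respiratory chain genes, 28 rose and 0 fell, or 29 and 0 adjusted over the list alone (median 0.17, camera adjusted p = 0.000171, and adjusted p = 0.0866 with an estimated correlation). Of these, NDUFV1 rose by 0.42 and ATP5F1A by 0.41, the latter not called without CD201-only replicate 2 (adjusted p = 0.0609).

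Lists not called by camera included genes with large changes. Of 8 blood markers, 3 rose and 3 fell, with CD68 at -2.60 and CD14 at -1.78. The blood median was 0.25 and its mean -0.37, and camera gave the lower direction (adjusted p = 0.749). Of 13 keratinocyte markers, 6 rose and 3 fell, or 6 and 4 adjusted over the list alone, with KRT14 at -3.05 and KRT16 at -1.98. The keratinocyte median was 0.11 and its mean -0.08, and camera gave the higher direction (adjusted p = 0.79). Of 25 p53 targets and CDK inhibitors, 9 rose and 6 fell, or 9 and 7 adjusted over the list alone, with CDKN2B at -1.18 and CDKN1A at -0.78. The p53 median was 0.04 and its mean -0.03, and camera gave the lower direction (adjusted p = 0.709).

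Of 11 endothelial markers, 3 rose and 5 fell, with ROBO4 at -1.61 and FLT1 at -1.26, and the median of 0.000465 differed in sign from the mean of -0.23 and from camera (adjusted p = 0.267). Of 25 unfolded protein genes, 13 rose and 6 fell (median 0.10, adjusted p = 0.422), with CHAC1 at -1.30 and PHGDH at 0.80. Of 24 cholesterol genes, 8 rose and 5 fell (median 0.05, adjusted p = 0.79), with INSIG1 at -0.68. Of 24 glycolysis genes, 16 rose and 6 fell (median 0.18, adjusted p = 0.0944, and 0.0145 without the filter), with SLC2A3 at 0.97 and PFKFB3 at -0.91. Of 7 neural genes, 3 rose and 2 fell (median 0.13, adjusted p = 0.709), with STMN2 at -0.67 and DLL3 at 0.51. Of 9 trophoblast and amnion genes, 5 rose and 1 fell (median 0.28, adjusted p = 0.267), with HAND1 from 35.71 ± 1.37 to 93.33 ± 0.807 FPKM (1.36) and GABRP at 1.09. HAND1 was the 1 called gene of 3 in the mesoderm and endoderm list. These adjusted p values are camera's.

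limma called 7165 genes, 4370 higher and 2795 lower, a share of 61% higher that median-ratio rescaling moved to 48.1%. At a change of at least 2-fold 83 rose and 503 fell, and 7746 genes had an unadjusted p under 0.05. camera called 16 lists at the preset correlation and 4 with an estimated one, and fry called 24.

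Double-negative cells were compared with CD201-only cells to ask what differs with the absence of CD201 among cells negative for CD13. The factors POU5F1 and SOX2 and 17 of 22 genes of pluripotent cells were higher, and 11 of 13 keratinocyte markers and 11 of 20 epithelial genes were lower. camera called these 3 lists, with adjusted p = 0.166, 0.166 and 0.175 with an estimated correlation. POU5F1 rose from 520.9 ± 14.3 to 893.4 ± 3.13 FPKM (0.78, SE 0.0291, adjusted p = 4.26e-06) and SOX2 from 463.9 ± 14.1 to 746.7 ± 0.351 FPKM (0.69, adjusted p = 4.03e-06). KLF4 was not called (-0.03, adjusted p = 0.487). MYC fell by 0.09 (adjusted p = 0.0298), and this call was lost in limma without the trend (adjusted p = 0.133). It was also lost when any double-negative or CD201-only library was left out (log2 changes from -0.0708 to -0.107) and with the double-negative libraries averaged (-0.0889). PROCR fell by 1.40 (adjusted p = 3.54e-06) and ANPEP rose by 0.31 (adjusted p = 0.000301).

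HAND1, a transcription factor of heart, amnion and trophoblast, fell from 93.33 ± 0.807 to 17.11 ± 0.879 FPKM (log2 change -2.38, SE 0.0447, adjusted p = 2.9e-07). CLDN4, a tight junction protein, fell from 46.19 ± 0.724 to 8.666 ± 0.628 FPKM (-2.29). LYPD2, a surface protein, fell from 30.78 ± 0.335 to 4.251 ± 0.455 FPKM (-2.60), RNASE1, a secreted ribonuclease, from 93.54 ± 0.315 to 20.25 ± 1.2 FPKM (log2 change -2.15), the long noncoding RNA LINC01405 by 2.58 and the phosphodiesterase PDE2A by 2.27. Beside SCARNA20 and SNORA3B, which were listed at 0 in CD201-only cells, the largest rises were MT1H from 15.47 ± 1.4 to 64.12 ± 3.26 FPKM (1.99), the chemokine CXCL8 from 1.57 ± 0.265 to 8.841 ± 1.46 FPKM (1.93), MT1G from 81.74 ± 1.76 to 303.3 ± 14.9 FPKM (1.88) and the monooxygenase MOXD1 from 12.64 ± 0.122 to 46.77 ± 0.125 FPKM (1.81).

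Of 13 keratinocyte markers, 1 rose and 11 fell (median -0.87), with the laminin chain LAMB3 at -1.89 and KRT6A, from 41.72 ± 0.223 to 11.55 ± 0.736 FPKM, at -1.77 (camera adjusted p = 9.11e-07, and adjusted p = 0.166 with an estimated correlation). Of 20 epithelial genes, 5 rose and 11 fell, or 6 and 11 adjusted over the list alone (median -0.38), with KRT19 at -1.28, KRT7 at -0.95 and RAB25 at -0.93 (camera adjusted p = 0.00162, and adjusted p = 0.175 with an estimated correlation). Of 22 genes of pluripotent cells, 17 rose and 3 fell (median 0.39), with LIN28A at 1.59, GDF3 at 0.83, LEFTY1 at 0.80 and DNMT3B at 0.72 (camera adjusted p = 0.000462, and adjusted p = 0.166 with an estimated correlation). Of 21 secreted inflammatory genes, 16 rose and 1 fell, or 17 and 1 adjusted over the list alone (median 0.80), with IL1B at 1.70 and CXCL8 above (camera adjusted p = 9.45e-06, and adjusted p = 0.166 with an estimated correlation). Of 24 interferon response genes, 13 rose and 0 fell, or 14 and 1 adjusted over the list alone (median 0.28). IFI27 rose from 196.4 ± 0.223 to 509.1 ± 1.87 FPKM (1.37) and the RNA sensor IFIH1 by 1.2 (camera adjusted p = 0.00149, and adjusted p = 0.251 with an estimated correlation).

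Of 25 p53 targets and CDK inhibitors, 1 rose and 15 fell (median -0.16), with CDKN2C at -0.58 and PHLDA3 at -0.55 (camera adjusted p = 0.00013, and adjusted p = 0.166 with an estimated correlation). Of 25 unfolded protein genes, 15 rose and 1 fell, or 16 and 2 adjusted over the list alone (median 0.25), with ASNS, asparagine synthetase, at 0.78 and CHAC1 at 0.78 (camera adjusted p = 0.00162, and adjusted p = 0.166 with an estimated correlation). Of 13 AP-1 genes, 2 rose and 8 fell (median -0.26), with JUN at -0.78, FOSL2 at -0.73, JUNB at -0.64 and FOSB at -0.54. camera called the AP-1 list (adjusted p = 0.00754, and adjusted p = 0.175 with an estimated correlation) and did not after the GC correction (adjusted p = 0.0506). Of 40 ribosomal protein genes, 0 rose and 8 fell, or 0 and 6 adjusted over the list alone, with RPS3 at -0.12 and RPLP1 at -0.11. Neither gene was called under quantile normalization (RPS3 at -0.04, adjusted p = 0.138, and RPLP1 at 0) or in limma without the trend (adjusted p = 0.0512 and 0.0664). Quantile normalization gives a gene of the same rank in every library the same value, so for RPLP1 that setting could not show a difference. camera called this list lower (median -0.04, adjusted p = 0.0146, and adjusted p = 0.213 with an estimated correlation), and quantile normalization turned its median to 0.03 (adjusted p = 0.166). Without double-negative replicate 2 its adjusted p was 0.0642.

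Among lists not called by camera, 20 of 37 fibroblast and matrix genes rose and 12 fell (median 0.13, adjusted p = 0.156). Lysyl oxidase LOX rose from 40.92 ± 1.88 to 144.3 ± 2.54 FPKM (1.79), FN1 by 1.32 and LOXL2 by 1.07, and S100A4 fell from 2566 ± 3.81 to 1270 ± 1.41 FPKM (-1.01). Of 22 mesenchymal genes, 5 rose and 10 fell, or 6 and 10 adjusted over the list alone (median -0.09, adjusted p = 0.0535), with CDH2 at 1.11, SNAI1 at -1.0, TWIST2 at -0.96 and FOXF2 at -0.73. Of 22 TGF-beta response genes, 8 rose and 11 fell, or 9 and 11 adjusted over the list alone (median -0.06, adjusted p = 0.155), with TGFBI at -1.43. Of 25 YAP and TEAD targets, 6 rose and 12 fell, or 7 and 12 adjusted over the list alone (median -0.12, adjusted p = 0.102), with ANKRD1 at -1.41, AXL at -0.85 and CTGF at 0.53. Of 13 contractile genes, 3 rose and 6 fell, or 4 and 7 adjusted over the list alone (median -0.07, adjusted p = 0.159), with ACTG2 at 1.62 and DES at -0.86. Of 11 endothelial markers, 3 rose and 7 fell (median -0.60, adjusted p = 0.0535), with KDR at 1.05 and S1PR1 at -1.0. Of 8 blood markers, 2 rose and 3 fell (median -0.23, adjusted p = 0.164), with CD34 at -1.79 and CD14 at 1.07. Of 27 genes that respond to cell handling, 7 rose and 13 fell, or 7 and 14 adjusted over the list alone (median -0.08, adjusted p = 0.0555), with EGR1 at 0.72. camera called the mesenchymal list lower without CD201-only replicate 1 (adjusted p = 0.0178), with the filter at 5 FPKM (adjusted p = 0.0286), after the GC correction (adjusted p = 0.0394) and without small RNA genes (adjusted p = 0.0498). Without CD201-only replicate 1 it also called the YAP (adjusted p = 0.0479) and cell handling (adjusted p = 0.0436) lists lower, and with the filter at 5 FPKM the contractile list (adjusted p = 0.0486). The endothelial list was called lower without either CD201-only library (adjusted p = 0.0433 and 0.0482), without double-negative replicate 2 (adjusted p = 0.0405), with double-negative libraries averaged (adjusted p = 0.0437), with a pseudocount of 0.1 (adjusted p = 0.0499) and without small RNA genes (adjusted p = 0.0498), and the fibroblast list was called higher under quantile normalization (adjusted p = 0.0471).

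camera called neither the proliferation nor the metabolism lists between these groups. Of 31 G2 and M-phase genes, 3 rose and 7 fell (median -0.06, adjusted p = 0.159), and of 29 S-phase genes, 3 rose and 7 fell, or 2 and 3 adjusted over the list alone (median -0.03, adjusted p = 0.165), in camera. UHRF1 fell by 0.46, and DLGAP5 (0.36), NDC80 (0.36), MCM6 (0.42), SDHC (0.28) and STARD4 (-0.46) were called. Leaving out a library ended these calls: DLGAP5 without replicate 1 of either group, NDC80 without double-negative replicate 2 or either CD201-only library, MCM6 and STARD4 without either double-negative library or CD201-only replicate 1, and SDHC without any single library of the pair of groups. Their adjusted p was then from 0.0603 to 0.131. The GC correction ended the calls of DLGAP5 (0.21, adjusted p = 0.102), NDC80 (0.22, adjusted p = 0.108) and SDHC (0.15, adjusted p = 0.117). Without the filter NDC80 (adjusted p = 0.0612), MCM6 (adjusted p = 0.0534), STARD4 (adjusted p = 0.0812) and SDHC (adjusted p = 0.0811) were not called. In limma without the trend STARD4 (adjusted p = 0.0503) and SDHC (adjusted p = 0.0573) were not called. With averaged double-negative libraries DLGAP5, MCM6, STARD4 and SDHC lost their calls. After the GC correction camera called the G2 and M-phase list lower (median -0.11, adjusted p = 0.00601). Of 43 chromatin regulators, 8 rose and 5 fell, or 5 and 3 adjusted over the list alone (median 0.05, adjusted p = 0.563), with RBBP7 at 0.57 and DNMT3A at 0.33. Of 39 respiratory chain genes, 7 rose and 4 fell, or 6 and 3 adjusted over the list alone (median 0.04, adjusted p = 0.61), with CYCS at 0.32. Of 24 cholesterol genes, 6 rose and 4 fell (median 0.02, adjusted p = 0.702). Of 24 glycolysis genes, 8 rose and 6 fell, or 10 and 6 adjusted over the list alone (median 0.07, adjusted p = 0.899), with SLC16A3 at -0.65 and SLC2A1 at -0.48. Of 7 neural genes, 3 rose and 4 fell, with MAP2 at 1.05 and DLL3 at 0.91, and the median of -0.19 differed in sign from the mean of 0.08 (adjusted p = 0.786, lower). Of 9 trophoblast and amnion genes, 3 rose and 4 fell (median -0.07, adjusted p = 0.329), and of 3 mesoderm and endoderm genes FOXA1 rose (1.18) and HAND1 fell.

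limma called 4632 genes between double-negative and CD201-only cells, 2620 higher and 2012 lower, a share of 56.6% higher that median-ratio rescaling moved to 47.1% and quantile normalization to 50.2%. At a change of at least 2-fold 126 rose and 144 fell. Without double-negative replicate 1 the count was 2888 and without replicate 2 it was 3040. camera called 9 lists at the preset correlation and 0 with an estimated one, while fry called 20, and 5762 genes had an unadjusted p under 0.05.

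The position of CD201-only cells between the other groups was taken over 815 genes that limma's F test called and that differed by at least 2-fold between double-negative and double-positive cells. On a scale from 0 at double-positive to 1 at double-negative, the median gene lay at 0.725, and at 0.725 and 0.727 from the replicate 1 and replicate 2 libraries alone. The median was 0.876 for the 570 genes lower in double-negative cells and 0.475 for the 245 higher genes. CD201-only cells lay between the others for 66.5% of these genes, beyond double-negative cells for 28.1% and below double-positive cells for 5.4%. Genes lower by at least 2-fold in both double-negative and CD201-only cells numbered 381, against 23.5 for independent lists, and genes higher in both numbered 22, against 1.67. Simulated runs with no true change gave at most 1 and 0 genes in common, but they leave out the effects. Both comparisons share the double-positive libraries, which were not split between them here, so part of the overlap may come from that sharing.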

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

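Of 230 named gene results, all but 16 kept their direction and their side of the threshold under the alternatives run for single genes, which leave out the 2-fold minimum. Of 4325 recomputed values 62 lost a call, 7 gained one and 1 lost its call with a change of sign. Apart from the 6 genes always named, these genes were picked as called genes with the largest changes, among all genes or in a list. These counts therefore do not describe how stable calls are in general. Of 75 list results 11 changed in 1347 recomputed values, without counting the estimated correlation and fry. The GC correction, the averaged double-negative libraries and the removal of small RNA genes were chosen after seeing the data.

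A minimum change of 2-fold left 816 genes between double-negative and double-positive cells, 586 between CD201-only and double-positive cells and 270 between double-negative and CD201-only cells, which follows from the stricter rule. The other settings gave 6070 to 8777, 5562 to 7345 and 3580 to 4867 genes. The number of genes tested differed, with 8272 at the filter of 5 FPKM and 19803 without a filter. Similar totals need not hold the same genes. Of the 8130, 7165 and 4632 genes called in the main analysis, 6177, 6045 and 3361 were also called after the GC correction. Of these, 27, 0 and 2 had the opposite sign. Under median-ratio rescaling 6643, 6024 and 4176 were also called. With 1 library left out the counts were 6851 to 7966, 5969 to 6782 and 2888 to 4903, where the lone library is assumed to vary like the others. Averaging the double-negative libraries gave 2818 genes in the last comparison, as fewer samples enter. With the replicate block limma called 8110, 7189 and 4590 genes. Replicate differences correlated across all genes at 0.0761 (double-negative with CD201-only), -0.0727 (double-negative with double-positive) and 0.117 (CD201-only with double-positive). Over 4691 well expressed genes the values were -0.0412, -0.0433 and 0.399. For those genes CD201-only and double-positive replicates thus shared a difference that double-negative replicates did not, and its cause was not tested. With the block PROCR was called lower in CD201-only than in double-positive cells (-0.13, adjusted p = 0.0222), camera called the endothelial and mesenchymal lists lower in double-negative than in CD201-only cells (adjusted p = 0.0428 each), and no other named gene or list changed its call. An estimated correlation left 0, 4 and 0 lists, where camera also tests on only 3 residual degrees of freedom. fry called 20 lists between double-negative and CD201-only cells, since it asks only whether genes move one way. Leaving out 1 library gave 20, 16 and 9 to 13 lists.

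The position of CD201-only cells was 0.715 and 0.716 with pseudocounts of 0.1 and 0.5, 0.74 without a filter, 0.721 with the filter at 5 FPKM, 0.732 under quantile normalization, 0.756 under median-ratio rescaling, 0.805 after the GC correction, 0.727 with averaged double-negative libraries, and 0.715 to 0.731 with 1 library left out. The cause was not tested.

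Under quantile normalization RPL8 in CD201-only against double-positive cells changed sign (-0.0481, limma adjusted p = 0.202). So did the ribosomal protein list in double-negative against CD201-only cells (0.0307, camera adjusted p = 0.166). Both lost their calls and neither was called the other way, and the cause was not tested. fry gave the neural list the higher direction at medians of -0.0788 against double-positive and -0.192 against CD201-only cells, where the means were 0.192 and 0.0803. Small changes were often missed in simulation: with 2 libraries per group, 29.6% of genes changed 1.2-fold were recovered between double-negative and double-positive cells. The simulation changed far fewer genes than were called in the data, which makes the threshold stricter. This share therefore does not give the recovery in the data.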

Other observations

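Genes that set CD201-only cells apart from both other groups were chosen after their values were seen. In CD201-only cells 17 genes were called at least 2-fold higher than in each of the other groups and 30 at least 2-fold lower. Under quantile normalization these were 19 and 24, under median-ratio rescaling 17 and 27, and after the GC correction 15 and 26, of which 14 and 25 were among the main ones. The higher genes include HAND1, a transcription factor of heart, amnion and trophoblast, at 17.11 ± 0.879 FPKM (SD, n = 2) in double-negative, 93.33 ± 0.807 in CD201-only and 35.71 ± 1.37 in double-positive cells. TH, tyrosine hydroxylase of catecholamine synthesis, was at 2.088, 10.02 and 3.251 FPKM in the same order, SFN, an epithelial 14-3-3 protein, at 21.33, 57.22 and 22.43, and CRIP1, a LIM domain protein, at 100.3, 220.7 and 99.3. The lower genes include the inflammatory genes CXCL8, IL1B, PTX3, MMP1 and MMP3, the matrix genes FN1, LOX at 144.3 FPKM in double-negative and 40.92 in CD201-only cells, and COL10A1, a collagen of growing cartilage, at 43.27, 11.74 and 39.36 FPKM.

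The metallothioneins, which bind zinc and copper, were also chosen after their values were seen. Of 10 tested members, 8 rose and 0 fell in double-negative against double-positive cells (median 1.17), 5 rose and 1 fell in CD201-only against double-positive cells (median 0.48), and 8 rose and 0 fell in double-negative against CD201-only cells (median 0.67). MT1X was at 984.6 ± 47.5 FPKM in double-negative, 623.3 ± 2.13 in CD201-only and 363.3 ± 0.302 in double-positive cells, MT2A at 987.1, 631.3 and 642.8, and MT1F at 20.35, 8.357 and 5.178. Reads can be shared among members of this family.

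The tests in the rest of this part, apart from the camera tests of lists without the GC correction, were chosen only after the result was seen. In double-negative against double-positive cells POU5F1 and SOX2 were higher while KLF4 and MYC were lower. A scaling of whole libraries moves every gene alike. The smallest gap in log2 change between a gene of one pair and a gene of the other was 1.15, so scaling does not account for this pattern. After the GC correction the gap was 1.08. That correction used the GC content of annotated transcripts and not of the constructs. It therefore cannot decide on a GC effect for reads that come from the vectors. Within each construct the ratio hardly moved: POU5F1 to SOX2 was 1.2, 1.12 and 1.16 in double-negative, CD201-only and double-positive cells and KLF4 to MYC 1.29, 1.24 and 1.28, with a largest log2 difference of 0.0915, while the first pair over the second was 5.59, 3.23 and 2.46. This is consistent with an unequal dose of the 2 constructs among the sorted cells. Regulation of the endogenous genes and reads shared with POU5F1 pseudogenes stay open, since vector reads were not separated here.

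KRT14, KRT16 and KRT6A were highest in double-positive cells. Keratinocytes in the double-positive libraries would raise that cell type's genes together, and against double-negative cells 9 of 13 tested keratinocyte markers, out of 21 listed of which 1 is in another list, were higher there (camera adjusted p = 0.000391, and adjusted p = 0.0626 with an estimated correlation). But 6 called markers, among them KRT5, COL17A1, LAMB3, SFN and TRIM29, were higher in CD201-only than in double-positive cells, and KRT5, the partner of KRT14, was at 2.23 FPKM in double-negative, 9.79 in CD201-only and 5.93 in double-positive cells, which argues against such cells as the whole source. The median log2 change of the 3 keratins in double-negative against double-positive cells was -2.80 before and -2.73 after the GC correction, which argues against the GC trend. Some such cells, a biological difference between the sorted groups and reads shared among keratin paralogs may still account for the pattern.

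Differences that involve double-negative cells followed transcript GC content, with a Spearman correlation across genes of -0.331 against double-positive and -0.417 against CD201-only cells. Genes are not independent replicates. Between replicates of one group the steepest correlation was 0.291, in the double-positive group, against sizes of 0.0237 and 0.0351 in the others, so a trend of this kind also arose without a difference of group. A library preparation effect and a biological one cannot be told apart for the trend itself, because each group was a separate set of libraries. Between double-negative and double-positive cells 19 of 20 called lists were still called in the same direction after the correction, and the exception was the blood list. Between double-negative and CD201-only cells, where the trend was steepest, the correction ended the AP-1 call (adjusted p = 0.0506) and added calls of the G2 and M-phase list (adjusted p = 0.00601) and the mesenchymal list (adjusted p = 0.0394).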
